A study of Mus musculus with 7 samples.

How the data were processed

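The series measured dimethylation of lysine 79 of histone H3 (H3K79me2) by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse bone marrow-derived macrophages. Per the labels' protocols, marrow of C57BL/6 mice was grown for 7 to 8 days in medium with a source of the growth factor M-CSF, and 1 µM SGC0946, an inhibitor of the H3K79 methyltransferase DOT1L, or the solvent DMSO was given during differentiation. Chromatin of 10 to 20 M cells, fixed with 1% formaldehyde for 10 min, was pulled down with an H3K79me2 antibody, and libraries from 10 ng of ChIP DNA were sequenced as single 50 bp reads to a nominal 40 M per sample. The growth protocol mentions wild-type and knockout mice without saying which gave these samples. The design text calls the 3 SGC0946 and 3 DMSO samples biological replicates. The labels name 1 input sample as well, which was not used here because the table analysed holds no column for it.

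The deposited table holds whole-number read counts for 29397 regions in the 6 ChIP libraries, with no scaling between libraries visible in the values. Per the submitters' processing notes, HISAT2, HOMER 4.11.1, bedtools 2.27.0, ChIPseeker 1.20.0 and R 3.6.3 were used with the mouse build mm10. Which tool called the regions or counted the reads, whether regions were called per sample or on pooled samples, how reads mapping to several places were treated, and whether duplicate reads were removed or libraries thinned is not given in the sources used here. Each of these steps could change the counts, and thinning or duplicate removal could change the totals between groups. The regions are a single shared set that do not overlap each other. Their lengths run from 500 to 190192 bp with a median of 984 bp, 8366 of them measure 500 bp, and they cover 123.05 Mb. Region coordinates were read as zero-based starts and are given 1-based. The total count per library was 16.7, 17.0 and 19.5 M in DMSO and 3.13, 3.01 and 2.95 M in SGC0946.

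Regions were assigned to genes by overlap with RefSeq gene spans of GRCm38.p6, the assembly that mm10 names, using Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Where a region overlapped several genes it took the coding gene with the longest overlap. In all, 1172 regions overlapped more than 1 coding gene, including those named below for Hnrnpf, Timm10, Hsdl1, Npc2, Rpl4 and Rab1a. The annotation used gave gene spans without exons or strands, so exonic and intronic positions were not separated. Where several regions carried the same symbol, the region with the highest mean count stood for the gene. Before the samples were averaged, pairs of libraries of the same group were compared over regions of at least 20 counts in the pair, and chi-square per degree of freedom lay between 1.32 and 2.38, so none of the pairs were within sampling noise of each other.

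Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, filterByExpr by group, Benjamini-Hochberg adjusted p under 0.05). The main scaling was the total count per library with all normalization factors at 1, so a log2 fold change from it is a change of the region's share of its library's counts. No spike-in chromatin is named in the labels, so the same test was also run on unscaled counts, with an equal library size for all libraries in keeping with the equal nominal depth. Fixed gene lists with at least 8 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 12 lists, and again with an estimated correlation. Totals and shares of counts per library were compared by exact 2-sided permutation tests, for which 3 against 3 libraries allow no p under 0.1. Percentages kept are mean SGC0946 counts over mean DMSO counts of unscaled data. Standard errors of log2 fold changes were derived from the fold change and its F value. The edgeR biological coefficient of variation was 3.57%, and figures were drawn with matplotlib 3.10.9.

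The edgeR step was tested on simulated counts for this comparison, drawn from the real library totals with 200 regions changed by known folds. The changed regions were drawn from those with a mean of at least 20 counts, and the dispersion was set to 0.002 for all regions. Of 22519 regions tested, it recovered 20% of the regions changed 1.25-fold, 52% of those changed 1.5-fold, 78% at 2-fold and 96% at 4-fold, with 11 false calls. These rates do not cover regions with fewer counts or data in which many regions change.

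The tests of regions, lists and the top share, the trend with mean count, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparison of total counts, with all its alternatives, was added after seeing the data. Named genes were the 8 regions with the highest and the 8 with the lowest fold change among those past the threshold with a mean of at least 50 counts and with all SGC0946 values on the same side of all DMSO values, the 2 members of each list with the smallest p, and Dot1l. Unnamed gene models were skipped. Results for some of these genes and for a family of genes are not reported here. A planned description of DMSO ChIP over input, with the 5 genes of highest ratio, could not be made. The 5 genes with the most DMSO counts per kb took its place and were chosen after the data were seen. Other genes named are counted members of a fixed list unless said otherwise.

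A measure of background was added after seeing the data. It used 1443 regions with under 15 DMSO counts per kb, which were in the shared set although DMSO had few reads there, and in each of them the SGC0946 library with the highest count was left out because it could be the library in which the region was called. Because low DMSO counts picked these regions, the density measured for DMSO is biased down, which also bears on the settings that rest on it. Alternatives tried were TMM factors, DESeq2 1.42.0 size factors and Wald test, limma-voom, cyclic loess, scaling on the 25% of regions with the lowest counts per kb, unscaled counts, no count filter, a mean of at least 50 counts, a replicate block, each library left out in turn, a test against a 1.2-fold change, autosomes alone, counts summed per gene and, added later, scaling on the sparse regions, leaving them out, and subtracting their density from each count.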

Results

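H3K79me2, a histone mark laid down by DOT1L over the transcribed part of active genes, was mapped in macrophages grown from mouse bone marrow with the DOT1L inhibitor SGC0946 (1 µM) or with DMSO. There were 3 libraries per group, described as biological replicates. The table gave read counts in 29397 regions, and 95.5% of the regions overlapped an annotated gene and 93.2% a protein-coding gene. The mean total was 17.8 ± 1.54 M counts per library (SD, n = 3) with DMSO and 3.03 ± 0.0922 M (SD, n = 3) with SGC0946. All coordinates are on mm10, and each region is placed in the span of a gene without saying which exons or introns it covers.

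The regions lay over genes that macrophages use. All 28 genes of the macrophage identity list, all 27 of the cholesterol synthesis and uptake list and all 30 ribosomal protein genes were overlapped by a region, against 43.4% of all 21900 coding genes. Cell cycle genes (24 of 24) were covered as fully, and fatty acid synthesis (19 of 25), inflammatory (22 of 34) and interferon genes (15 of 24) less so. Genes of other cell types were mostly without a region: 4 of 24 markers of other blood cells (Klf1, Lck, Mpo and Zbtb46), 2 of 18 stromal and endothelial markers (Cxcl12 and Runx2) and 1 of 28 genes silent in blood cells (Gata4) had any. With DMSO the densest genes were Sirpa, an inhibitory receptor of myeloid cells, with 570 counts per kb, Rbpj, the transcription factor of Notch signalling, with 557, the adaptor Grb2 with 494, the small GTPase Rap1b with 479, and Npc1, which exports cholesterol from lysosomes, with 478. These 5 were chosen after the data were seen. The input sample was not used here, so densities are not relative to input.

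The comparison of SGC0946 with DMSO asks how far inhibiting DOT1L lowered the mark and whether genes differed in what they kept. The reads counted in the regions fell to 17.1% of the DMSO level, a 5.86-fold difference, and the lowest DMSO library held over 5 times the counts of the highest SGC0946 library (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). This comparison of totals was chosen after the data were seen. On unscaled counts, 24820 of 24895 tested regions fell and 5 rose (edgeR quasi-likelihood test, adjusted p under 0.05), with a median log2 fold change of -2.63. Scaling by library totals brought that median to -0.09 over regions and -0.27 over genes. The region of Dot1l itself (chromosome 10, 80754995 to 80767800) fell from 3750 ± 298 to 606 ± 44.2 counts (SD, n = 3), 16.2% of DMSO (adjusted p = 1.7e-130 on unscaled counts), and its share of the library did not change by the test (log2 -0.08, adjusted p = 0.265). Among the 11055 regions with a mean of at least 50 counts, every region kept between 7.56% and 79.7% of its DMSO count. Over the 23367 regions tested on library totals the median was 16.1%, and the middle 50% lay between 13.2% and 20.9%.

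The size of the fall depends on the unknown number of reads sequenced per library. In the 1443 regions where DMSO had under 15 counts per kb, SGC0946 libraries had 5.25 ± 1.08 counts per kb and DMSO libraries 4.23 ± 0.381 (SD, n = 3). These regions were picked for low DMSO counts, which favours a low DMSO value. The SGC0946 library with the highest count was left out in each region, which favours a low SGC0946 value.

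**Figure D1:**
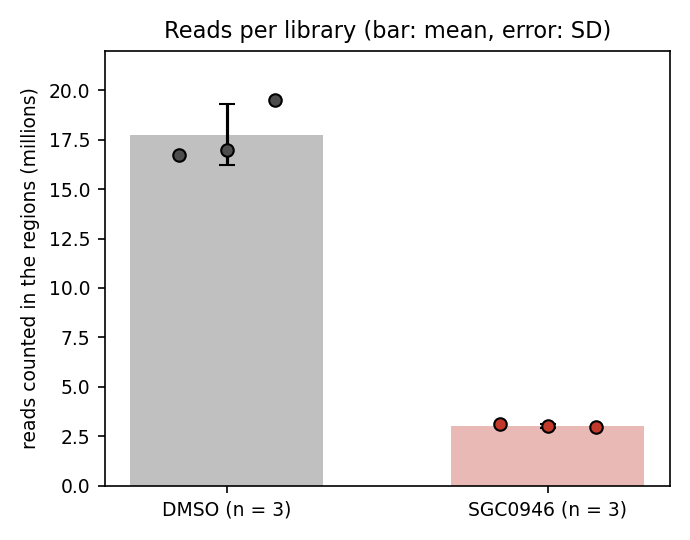
Reads counted in the 29397 regions per library, in M reads; points are libraries, bars the mean and error bars the SD of 3 libraries. The DMSO libraries lie between 16.7 and 19.5 M and the SGC0946 libraries between 2.95 and 3.13 M.

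Cd40, a costimulatory receptor of antigen-presenting cells, went against the general fall. Its region of 1696 bp (chromosome 2, 165062059 to 165063754) rose from 30.3 ± 3.06 counts with DMSO to 54 ± 7.81 with SGC0946 (SD, n = 3), a log2 fold change of 0.83 ± 0.24 (SE, adjusted p = 0.000433, edgeR on unscaled counts). A further Cd40 region of 701 bp (chromosome 2, 165070517 to 165071217) rose from 14 ± 3.46 to 28.3 ± 5.69 counts (adjusted p = 0.0013). The other 3 unscaled rises were small regions at Klhl23 (5 to 14.7 counts), Clec2g (5.67 to 11 counts) and the gene model Gm34259 (12.3 to 25 counts), named here because of their values. With SGC0946 all these regions had between 16.7 (Klhl23) and 40.4 (Cd40) counts per kb, and with DMSO between 5.71 (Klhl23) and 20.0 (Cd40). The regions of Klhl23 and Clec2g (11.3 with DMSO) had under 15 DMSO counts per kb. Such low DMSO counts leave the count filter to be passed through SGC0946, so these calls say nothing about the genes. The counts of Clec2g also overlapped between the groups. With scaling on the sparse regions, 3 rises were left in all.

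Relative to the fall of the whole library, a small set of heavily marked genes kept most of its counts. Tra2b, a splicing regulator (chromosome 16, 22249189 to 22266247), went from 7187 ± 789 to 5730 ± 246 counts (SD, n = 3) and kept 79.7%. Rbpj kept 72.4%, Psap, the precursor of the lysosomal saposins, 71.9%, Rap1b 70.5%, the splicing factor Srsf3 66.7%, the GTPase Cdc42 65.3% and the RNA-binding protein gene Hnrnpf 64.7%. Their shares of the library rose by log2 2.22 for Tra2b down to 1.92 for Hnrnpf, with adjusted p between 3.5e-56 for Rbpj and 7.5e-49 for Srsf3, while their unscaled counts fell by log2 -0.33 to -0.63. At the other end, Cxxc1, which encodes a CpG-binding subunit of H3K4 methyltransferase complexes, went from 188 ± 23.3 to 14.7 ± 0.577 counts and kept 7.82%. Timm10 kept 8.22%, Selenow 8.68%, Hsdl1 8.69%, the channel gene Panx1 8.71%, Dpy19l4 8.79%, the heparanase gene Hpse 8.82% and Tacc1 8.96%. The shares of these genes fell by log2 -1.12 (Cxxc1, adjusted p = 8.6e-06) to -0.93 (Tacc1, adjusted p = 4.4e-21). The regions of Hnrnpf, Timm10 and Hsdl1 each overlapped 2 coding genes, so their counts cannot be credited to the named gene alone.

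Of 23367 regions tested on library totals, 1440 rose and 5439 fell in share, so that 20.9% of the calls were rises. At the level of genes, 841 of 8643 rose and 4068 fell. The split moved with the processing: rises were 33.0% of the calls with TMM factors, 33.3% with DESeq2 size factors, 47.0% with the DESeq2 Wald test (which also brought its own size factors and tested all regions), 51.1% with cyclic loess and limma-trend, 33.8% without a count filter, 12.4% among regions with a mean of at least 50 counts, 10.0% with scaling on the sparsest 25% of regions and 8.48% once background was subtracted. It was 31.9% without SGC0946 replicate 3, where 28733 regions were tested.

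**Figure D2:**
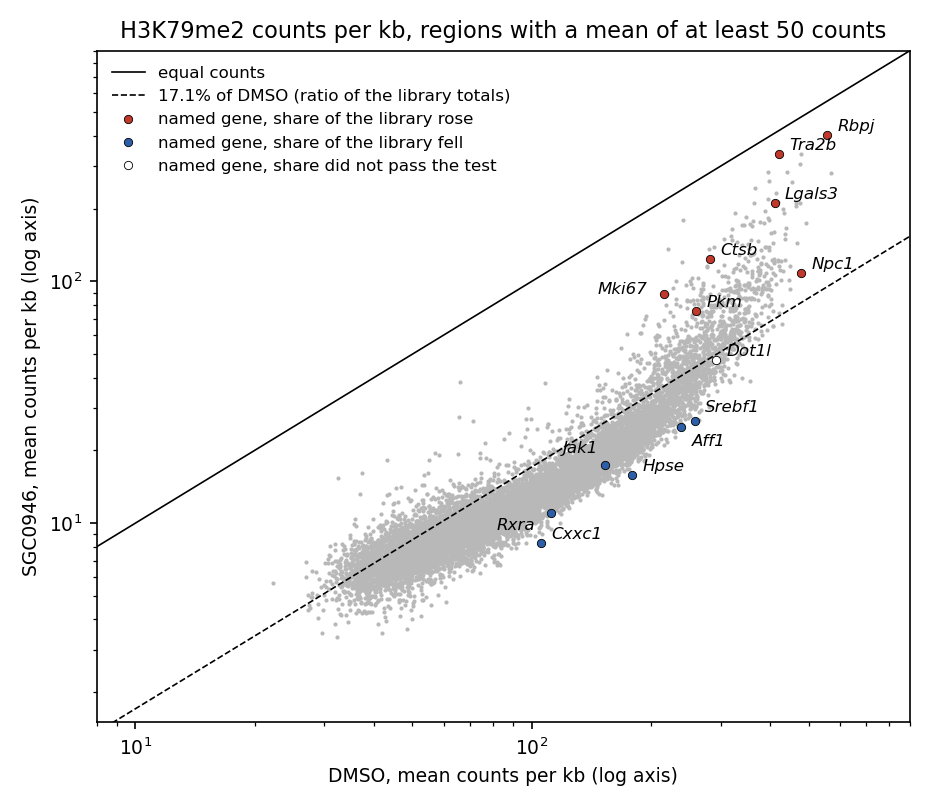
Mean H3K79me2 counts per kb with DMSO (x) and SGC0946 (y), both on log axes and unscaled, for regions with a mean of at least 50 counts; each value is the mean of 3 libraries. All regions lie under the line of equal counts; of the labelled genes Rbpj and Tra2b lie closest to it, and Cxxc1, Rxra and Hpse lie under the dashed line at 17.1%.

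The counts that remained were more concentrated. The 10% of regions with the most counts per kb held 67.7 ± 0.309% of a DMSO library and 74.6 ± 1.41% of an SGC0946 library (SD, n = 3, exact permutation p = 0.1, the smallest possible). By the same ranking the top 5% went from 46.0 ± 0.307% to 57.9 ± 1.40%, and the top 20% only from 86.9 ± 0.21% to 88.4 ± 1.06%. A different ranking, by mean count without regard to length, gave another picture. In the 10% of tested regions with the most counts, 611 regions rose and 1371 fell in share, with a median log2 fold change of -0.24. In the next 10%, 1865 regions fell and 91 rose (median -0.40). The 4 groups of 10% with the fewest counts had medians between 0.19 and 0.32. Across regions, which are not independent replicates, the log2 fold change went down with the mean count (Spearman rho -0.444). This trend turned to 0.289 once background was subtracted and to 0.0933 with cyclic loess. Both settings act on the trend by construction. Cyclic loess evens it out, and subtraction raises the relative share of dense regions in SGC0946. On library totals the trend weakened to -0.30, -0.276 and -0.290 without DMSO replicate 1, 2 or 3, and to -0.336 and -0.288 without SGC0946 replicate 1 or 2. Leaving out a library also changed which regions passed the count filter. There were 13526 to 13597 without a DMSO library and 28403 to 28733 without an SGC0946 library, against 23367. Whether the libraries or the changed set of regions moved the trend was not separated.

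In the lipid gene lists, a few genes of sterol synthesis and its control stood apart from the rest of the pathway. The synthase gene Hmgcs1 (4874 ± 461 to 1597 ± 81.4 counts; SD, n = 3) kept 32.8%, and its share rose by log2 0.94 (adjusted p = 9.7e-31). The sterol sensor gene Insig1 (23.4% kept) and the oxidase gene Msmo1 (21.5%) rose in share as well (log2 0.45 and 0.33, adjusted p = 1.0e-07 and 3.8e-07), while the unscaled counts of these genes fell. The 13 members called lower in share include the sterol regulator Srebf2 (11.7% kept) and the synthesis enzymes Cyp51 (11.8%) and Lss (10.8%). Of the 27 genes, 5 rose, 13 fell and 9 did not pass (5 and 14 adjusted over the list alone), and the list did not differ from other genes (camera adjusted p = 0.336, direction higher, while the median lay 0.06 under that of all genes).

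Genes of fatty acid and triglyceride synthesis mostly fell in share as well. Srebf1, the transcription factor of lipogenesis (chromosome 11, 60204856 to 60220289), went from 3979 ± 305 to 410 ± 32.1 counts and kept 10.3% (log2 share -0.73 ± 0.05 SE, adjusted p = 5.0e-19), and Acly, Acaca and Fasn kept 12.2%, 12.6% and 14.3%. Scd2, a stearoyl-CoA desaturase, kept 27.2% and rose in share by log2 0.67 although its unscaled counts fell. In this list 2 genes rose, 12 fell and 5 of 19 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.44). Among cholesterol efflux genes and targets of the sterol-sensing receptor LXR, Rxra, the receptor's partner, kept 9.80% (log2 share -0.81, adjusted p = 5.7e-20), Scarb1, an HDL receptor, 10.7% (log2 share -0.68, adjusted p = 7.1e-19), Abcg1 13.2% and Abca1 14.0%. Npc1 kept 22.6%, Npc2 23.4% and Arl4c 25.9%, and these rose in share while falling in unscaled counts. The call of Npc1 was lost with scaling on the sparsest 25% of regions (adjusted p = 0.346). The list had 4 rises, 7 falls and 6 of 17 genes that did not pass (5 and 7 adjusted over the list alone; camera adjusted p = 0.44).

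Inflammatory and interferon genes went both ways in share. Apart from Cd40, whose share rose by log2 3.37 ± 0.20 (SE, adjusted p = 4.4e-23), the receptor gene Tlr4 (20.8% kept) and the NF-kB subunit gene Rel (22%) rose in share, while their unscaled counts fell. The NF-kB genes Nfkb1 and Rela kept 11.6% and 10.4% and fell in share by log2 -0.56 and -0.72 (adjusted p = 2.3e-15 and 3.4e-07), as did Cd80, Nlrp3, Myd88 and Casp1. Tnf kept 16.6% (adjusted p = 0.786 for its share). Of 22 inflammatory genes, 3 rose, 6 fell and 13 did not pass (3 and 7 adjusted over the list alone; camera adjusted p = 0.336; median log2 share -0.10, mean 0.09). In the interferon list the kinase gene Jak1 kept 11.3% (log2 share -0.59, adjusted p = 7.0e-20) and Ifi35 11.6% (log2 share -0.55, adjusted p = 7.1e-06, lost at 0.270 with cyclic loess). This list, in which Mx1 is annotated as a pseudogene and was tested beside the 15 coding genes, had 2 rises, 7 falls and 7 of 16 genes that did not pass (2 and 8 adjusted over the list alone; camera adjusted p = 0.977, direction lower, while the median lay 0.01 above that of all genes).

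Macrophage identity genes kept more than most. Lgals3, which encodes galectin-3 (chromosome 14, 47372129 to 47383980), kept 51.6% of its counts (4863 ± 375 to 2507 ± 180; SD, n = 3), the cathepsin gene Ctsb 43.8%, Gpnmb 34.9% and the transcription factor gene Maf 33.5%, with log2 shares of 1.59 and 1.36 for Lgals3 and Ctsb (adjusted p = 2.7e-44 and 2.9e-41) and falling unscaled counts for all 4. Mitf (11% kept), Mertk (11.5%), Tfec (12.7%), Runx1 (13.4%) and Cebpa (13.9%) fell in share, and the lineage regulator Spi1 (17.2%) and the receptor gene Csf1r (18.8%) did not pass. Of 27 genes, 13 rose, 5 fell and 9 did not pass (15 and 5 adjusted over the list alone), with a median log2 share 0.51 above that of all genes (camera adjusted p = 3.6e-08; adjusted p = 0.152 with an estimated correlation). Housekeeping genes did likewise. For neither list was read density separated from membership. Within the 10% of tested regions with the most counts, the densest 10% kept a median of 25.6%, against 14% for the others. Over all tested regions, those with few counts included, the log2 share instead went down with CPM per kb (Spearman rho -0.284). Read density among heavily marked regions could still account for the place of both lists. Actb (32.0% kept), Pgk1 (31.5%), Gapdh (29.5%) and the pyruvate kinase gene Pkm (29.0%) rose in share, and 14 of the 22 rose, 3 fell and 5 did not pass (15 and 3 adjusted over the list alone; median 0.60 above all genes; camera adjusted p = 1.9e-10; adjusted p = 0.259 with an estimated correlation), although all 22 fell in unscaled counts.

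Lysosome and phagocytosis genes went both ways. Psap, the lysosomal membrane protein gene Lamp1 (56.0% kept, log2 share 1.71, adjusted p = 1.8e-47), Hexa (28.4%) and the small GTPase Rab7 (26.7%) rose in share while their unscaled counts fell, whereas Tfeb, the transcription factor of lysosomal genes, kept 10.8% and fell, together with Neu1 (12%). Of 23 genes, 7 rose, 10 fell and 6 did not pass (7 and 12 adjusted over the list alone). The test called the list higher than other genes (camera adjusted p = 0.0195; adjusted p = 0.517 with an estimated correlation), its mean log2 share was 0.11 and its median -0.14. The call was lost without SGC0946 replicate 1, 2 or 3 (adjusted p = 0.0817, 0.0741 and 0.142), with no count filter (0.147) and with scaling on the sparsest 25% of regions (0.0524). On unscaled counts the median distances from all genes stayed the same for macrophage identity (0.50), housekeeping (0.60) and lysosome genes (0.13), but camera called none of these lists (adjusted p between 0.426 and 0.958).

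Ribosomal protein genes stayed close to the fall of the whole library. Rps9 kept 28.9% (log2 share 0.76, adjusted p = 5.4e-14), Rpl4 27.9% (log2 share 0.71, adjusted p = 4.1e-17) and Rps6 11.3%, and of 28 genes 5 rose, 3 fell and 20 did not pass (6 and 5 adjusted over the list alone; camera adjusted p = 0.0522). TMM factors and DESeq2 size factors brought this list past the threshold (adjusted p = 0.0138 and 0.0105), and so did cyclic loess (2.7e-06), background subtraction (0.00144) and leaving out SGC0946 replicate 1 (0.0455) or 2 (0.0486). All of these calls used the preset correlation. With an estimated correlation on library totals the camera adjusted p was 0.655.

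Genes of the DOT1L and elongation complexes more often fell than rose in share, as genes did in general (841 of 8643 rose and 4068 fell). Aff1 (chromosome 5, 103753865 to 103810662) and Kmt2a, both fused in leukaemia, kept 10.5% and 10.6% (log2 share -0.71 and -0.69, adjusted p = 4.0e-25 and 5.8e-19), and Mllt10, a DOT1L partner, kept 11.6%, while Ccnt2 (23.2%) rose in share with falling unscaled counts. The list had 2 rises, 9 falls and 10 of 21 genes that did not pass (3 and 12 adjusted over the list alone; camera adjusted p = 0.771, direction lower, while the median lay 0.08 above that of all genes). Of the 8 tested targets of MLL-AF9 and DOT1L in leukaemia, 3 rose, 3 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.336). Zeb2 kept 21.8% and rose in share by log2 0.35, a call lost with scaling on the sparsest 25% of regions (adjusted p = 0.556), and Cdk6 kept 11.8% and fell in share by log2 -0.53. Hoxa9 and Meis1 were among the list's members without a region.

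Among cell cycle genes, Mki67, which encodes the proliferation marker Ki-67, kept 41.1% (4896 ± 462 to 2012 ± 103 counts; SD, n = 3; log2 share 1.27, adjusted p = 3.0e-38) and Cdkn1a, the gene of the inhibitor p21, kept 20.4% (log2 share 0.26, adjusted p = 2.2e-05), both falling in unscaled counts. The call of Cdkn1a was lost with scaling on the sparsest 25% of regions (adjusted p = 0.791) and against a 1.2-fold change (0.600). Of 22 genes, 3 rose, 8 fell, with Ccnb1, Mcm2 and Plk1 among them, and 11 did not pass (3 and 9 adjusted over the list alone). The camera adjusted p of the list was 0.336, and 0.655 with an estimated correlation. With cyclic loess it was 0.0162 at the preset correlation. The lists of other cell types were too small to test. Mpo had 3.67 ± 3.06 counts with DMSO and 9 ± 2.65 with SGC0946, Lck 1.33 ± 0.577 and 5.67 ± 2.52 (SD, n = 3), in sparse regions of 500 bp. Both were called higher in share (adjusted p = 1.8e-07 and 4.0e-06, edgeR), as were all 195 tested regions with under 15 DMSO counts per kb, where low DMSO counts leave the count filter to be passed through SGC0946, so these calls say nothing about the genes. Runx2 went from 88.3 ± 22 to 17 ± 2 counts (adjusted p = 0.676 for its share).

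**Figure D3:**
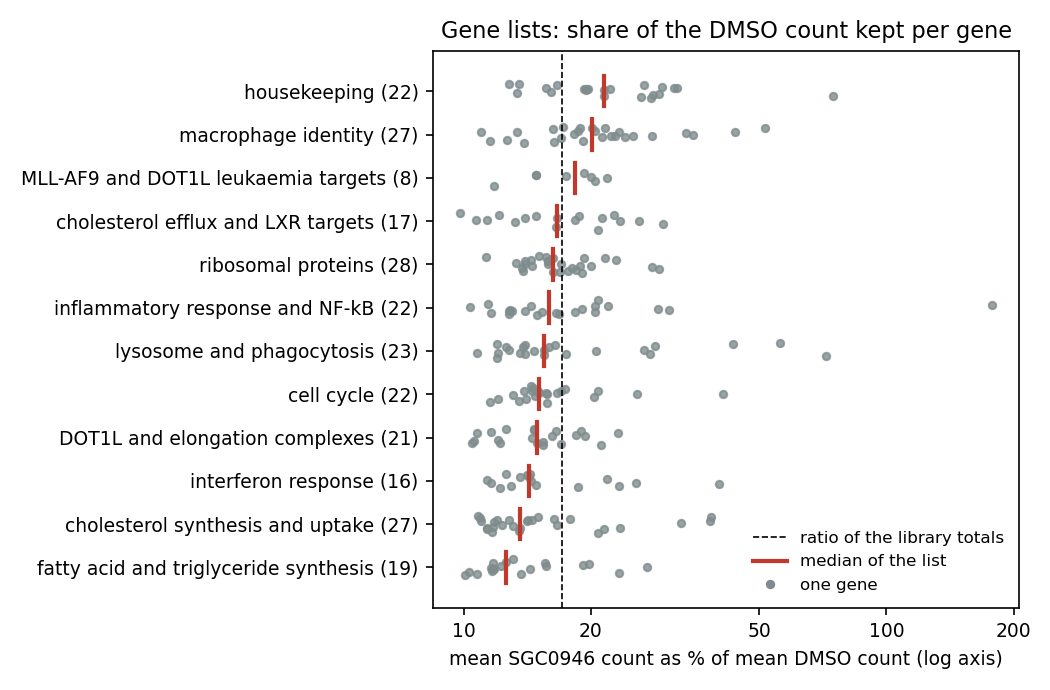
Mean SGC0946 count as a percentage of the mean DMSO count, on a log axis, for each tested gene of 12 fixed lists (number of genes in brackets); red bars are medians and the dashed line is the ratio of the library totals, 17.1%. Housekeeping (median 21.5%) and macrophage identity genes (20.1%) lie highest and fatty acid synthesis genes (12.6%) lowest, and Cd40 stands alone at 178%.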

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

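Of the alternatives tried, those on the sparse regions, on subtracted background and all those for the total count were chosen after seeing the data. Those that need the input (ChIP over input with other pseudocounts, ranking by input) could not be run. The fall of the total and the greater share of the top 10% of regions kept their direction under the alternatives run on them (for the total autosomes, the sparse-region settings, subtraction and each library left out, for the share 5% and 20% of regions and each library left out). For all results that moved or reversed, the cause was not tested, except for effects that follow by construction. Scaling to a common read number turns relative rises into falls. Cyclic loess evens out a trend of the fold change with mean count, and subtraction raises the relative share of dense regions in SGC0946. At this depth 23367 of 29397 regions passed the count filter. In simulated regions with a mean of at least 20 counts, 52% of 1.5-fold changes were recovered. Of the checks of single genes, 849 gave the same result, 5 were weaker, 2 stronger and 40 reversed, and of those of single lists 227 were the same, 12 weaker, 11 stronger and 2 reversed.

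The count of regions past the threshold was 6879 (edgeR), and 24825 on unscaled counts, 24935 with scaling on the sparse regions, 11776 with background subtracted, 3740 against a 1.2-fold change and 3194 with cyclic loess, where rises outnumbered falls (reversed). It was 6152 to 6810 with each library left out in turn. The count of lists was 3, against 0 on unscaled counts, 0 with the sparse regions, 0 with an estimated correlation, 5 with cyclic loess and 2 to 3 with a library left out. The fry test of limma, which tests a list against no change and not against other genes, called 6 lists, with fatty acid synthesis, interferon and DOT1L and elongation genes lower. On unscaled counts the tests of macrophage identity (median 0.5047 above all genes, adjusted p = 0.597) and lysosome genes (0.1279, adjusted p = 0.426) pointed down, although these distances hardly differed from 0.507 and 0.129 on library totals. The trend with mean count was -0.444, and 0.0933 with cyclic loess, 0.289 with background subtracted and -0.413 to -0.276 with a library left out. The total ratio was 5.86, and 7.08 with the sparse regions, 7.20 with background subtracted and 5.57 to 6.02 with a library left out. The gain of the top 10% was 6.16 to 7.56 percentage points with a library left out.

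Single genes that reversed did so under scaling to a common read number, where log2 values were, on unscaled counts and with the sparse regions: Tra2b -0.33 and -0.60, Rbpj -0.47 and -0.74, Psap -0.475 and -0.74, Rap1b -0.50 and -0.78, Srsf3 -0.59 and -0.86, Cdc42 -0.61 and -0.89, Hnrnpf -0.63 and -0.90, Scd2 -1.88 and -2.15, Lgals3 -0.96 and -1.23, Ctsb -1.19 and -1.47, Zeb2 -2.20 and -2.46, Pkm -1.79 and -2.06, Rpl4 -1.84 and -2.12, Rps9 -1.79 and -2.07, Lamp1 -0.84 and -1.10, Mki67 -1.28 and -1.55, Cdkn1a -2.29 and -2.57, Sirpa -1.03 and -1.30, Grb2 -1.49 and -1.76, Npc1 -2.14 and -2.40.

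The sample titles use the same replicate numbers in both groups, and whether a number stands for the same mouse is not known here. Deviations from the group mean correlated at 0.00921, -0.114 and -0.012 between libraries of the same number. With so few libraries this does not show that they are unpaired. The main test and the permutation tests treated them as unpaired. A replicate block gave 6616 regions (1414 higher and 5202 lower) and 3 lists, and with TMM factors 5632 regions and 4 lists.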

Other observations

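The tests of read number, pull-down, saturation and background in the regions with the fewest counts were chosen after the values they bear on had been seen; the other tests here were fixed before their results. Some non-coding RNA genes, named here because of their values, kept much of their counts. The region over Xist and its antisense partner Tsix (chromosome X, 103467899 to 103483354, where counts cannot be assigned to a strand) kept 61.7% of its DMSO counts (3417 ± 423 to 2109 ± 60.2; SD, n = 3). The region of the microRNA gene Mirlet7d kept 50.2%, that of Malat1, a nuclear long non-coding RNA, 46.2% (2574 ± 249 to 1190 ± 119), and that of its neighbour Neat1 23.5%. These rose in share of the library while falling in unscaled counts, whereas others such as Lncpint (17.5%, adjusted p = 0.534 in edgeR) and Mir24-2 (17.9%, 0.383) kept about the ratio of the totals. On chromosome Y the table held 4 regions, all between 90797465 and 90809859.

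In all, 23 of 11055 regions with a mean of at least 50 counts kept 50% or more. Beside the genes of the report they include the GTPase gene Rab1a (64.3%), the RNA helicase gene Dhx9 (58.6%), Osbpl8 (56.9%), the splicing regulator gene Mbnl1 (55.7%) and the chromatin remodeller gene Chd2 (51.4%). Together the 23 regions held 1.30 ± 0.0357% of the counts of a DMSO library and 4.67 ± 0.173% of those of an SGC0946 library (SD, n = 3).

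The fall of the total count was weighed against technical causes. Evenly fewer reads as the only difference between the groups would lower all regions alike. The spread of what was kept argues against this. In 4142 regions with a mean of at least 500 counts, the 95th percentile of the unsubtracted ratio was 2.61 times the 5th (27.6% against 10.6%). Between replicates this quotient was 1.16 to 1.42. A factor common to all regions leaves the quotient as it is. It therefore does not bear on how much of the fall of the total came from fewer reads. A weaker pull-down that scales all marked regions alike would also leave little spread, and the quotient was 4.61 once background was subtracted (26.2% against 5.68%). Subtraction itself widened this spread. Saturation of DMSO counts, left open below, would give unlike percentages under an even pull-down. The counts were thus not scaled by a single factor, but the spread does not decide whether a weaker pull-down accounts for the fall. In the sparse regions the DMSO density was 0.806 times that of SGC0946, whose library of highest count was left out in each region. These regions were picked for low DMSO counts, and the ratio followed the limit (0.529 under 6 counts per kb). The ratio does not decide whether fewer reads account for part or all of the fall. A loss of the mark under the inhibitor may account for the fall and is left as a hypothesis, and an uneven pull-down, duplicate removal and thinning of reads were not tested.

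The relative rises were weighed against background and saturation. Of the 611 rises in the 10% of regions with the most counts, 610 stayed past the threshold after background was subtracted. Subtraction took the same density from all regions of a library, and shares were then rescaled to the smaller totals. This step raises the relative share of dense regions in SGC0946, so such rises could hardly be lost. The test therefore does not decide whether a higher background accounts for part of them. Of 537 rises in the 40% of regions with the fewest counts, 51 stayed, which leaves the role of background open, since 193 were themselves sparse regions and 357, many of them the same regions, were not tested after subtraction; the 156 that were neither were all still higher, with a median log2 share of 0.95 (quartiles 0.72 and 1.18) against 1.21 (1.1 and 1.4) before, and 27 of them still passed. In the densest 10% of these top regions (234 regions) the 95th percentile of what was kept was 3.34 times the 5th (54.0% against 16.2%). This spread does not decide whether saturation of DMSO counts accounts for the rises. Capped DMSO counts could hide unlike levels at like densities, and such regions would also keep unlike percentages. Over all tested regions the log2 share went down with CPM per kb (Spearman rho -0.284). Among the top regions, though, the densest kept more (median 25.6% against 14% of the others), so saturation stays open. That these genes keep, or regain faster, more of the mark stays a hypothesis, and cross-reaction of the antibody was not tested.

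Genes of hnRNP and SR splicing factors may keep more of the mark than other genes, a hypothesis drawn from Tra2b, Srsf3 and Hnrnpf and tested on 27 members that had not been looked at. Of these, 16 rose and 5 fell in share, with Hnrnpc (36.2% kept), Ptbp3 (35.5%) and Hnrnpd (34.6%) highest and Hnrnph3 (12.9%) lowest, and their median was 0.67 above that of other genes (log2, camera adjusted p = 7.8e-14 over 6 families; adjusted p = 0.172 with an estimated correlation). On unscaled counts the counts of all named members were lower with SGC0946. Within the top regions the densest kept more (median 25.6% against 14% of the others), although over all tested regions the trend with density ran the other way. Read density or transcription rate could therefore account for the family's place, and neither was separated here.

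For actin assembly factors, 8 of 19 unseen members rose and 10 fell, with Actr2 (39.9% kept) and Actg1 (34.6%) highest (camera adjusted p = 0.000177; adjusted p = 0.172 with an estimated correlation; median 0.14 above other genes). Among these 19 is Cflar, which was matched by the start of its symbol and is not an actin factor (adjusted p = 7.4e-05 without it). Genes matched by the symbol start of translation initiation factors did not pass (camera adjusted p = 0.172), but they include kinases (Eif2ak1 to Eif2ak4) and inhibitors (Eif4ebp1 and Eif4ebp2) that are not such factors and that fell in share. Without these and Eif4enif1, a choice made after the result was seen, 11 of 39 rose and 13 fell (camera adjusted p = 0.0169; adjusted p = 0.156 with an estimated correlation), so whether this family keeps more of the mark stays open.

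The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 6879 regions and the highest of the others 0, so that 1 of the 10 splits gave as many. For the gene lists the real split called 3 and the highest of the others 4, and 3 of the 10 splits gave as many. Every other split puts libraries of both treatments on each side. Part of the difference between treatments stays in it, and the spread within its groups is larger. These counts therefore do not show what would be called without a treatment.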
